A study of Mus musculus with 18 samples.

How the data were processed

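Total RNA from E14 mouse embryonic stem cells was labelled with biotin and hybridised to Illumina MouseWG-6 V1.1 BeadChips, 1 array per sample. The 18 arrays form 6 groups of 3, defined by the shRNA (against Esrrb, or against GFP as control) and by the day (2, 4 or 6). The labels call the 3 arrays of a group biological replicates. The column headers show that the replicate number is also the BeadChip: each of 3 BeadChips held 1 array of each of the 6 groups. Each group had the same position on every BeadChip, so position and group cannot be told apart. All Esrrb arrays carry the same shRNA label, so other effects of that shRNA cannot be told apart from loss of Esrrb.

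The deposited probe intensity is, per the file headers, the mean intensity over the beads of a probe, summarised with BeadStudio 3.2.6 without normalization or background subtraction. The deposited detection score runs from 0 to 1 and rises with the signal, so the detection p was taken as 1 minus the score. The deposited bead number (unit: other) counts the beads behind each probe mean. Its median was 37 beads per probe, with a range of 3 to 107. A second table by the authors holds intensity values on a linear scale, normalized between arrays by a method not stated in the sources used here. The array medians of those values lie between 62.6 and 67.8. The identifiers in that table have no counterpart in the raw table, so its values could not be named and served only as an alternative for counts.

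The raw table holds 46643 probes under 34325 target names. RefSeq gene names (assembly GRCm38.p6, used for names only) matched 16079 target names as current symbols and updated 6654 through 1 unique synonym. A further 11565 names were kept as given, and 27 names that a spreadsheet had turned into dates or numbers were not named. No coordinates are given. The 355 probes for non-mouse sequences and control spots were left out of the tests of genes.

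Intensities were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected the background by the normexp model with the detection p-values, added an offset of 16, applied quantile normalization and took log2. Probes were kept when their detection p was under 0.05 on all 3 arrays of at least 1 group, which left 19458 probes. The probe with the highest mean over all 18 arrays stood for its gene, which left 14531 genes. The median raw intensity per array ran from 60.4 to 76.9, and 37.7% to 42.6% of probes were detected. For arrays, their number limits the precision.

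One linear model with 6 groups was fitted to all 18 arrays, so that the groups shared 1 estimate of each gene's spread (lmFit, contrasts.fit, eBayes). The contrasts were Esrrb shRNA minus GFP shRNA on each day, the 3 differences of these effects between days, and GFP shRNA at day 6 minus day 2. The Benjamini-Hochberg adjustment was applied per contrast, with a threshold of 0.05. Errors of fold changes are standard errors of that model, and all tests are two-sided. Each day has its own control arrays, so no control array is shared between days. Fold changes are Esrrb shRNA over GFP shRNA on the log2 scale unless stated otherwise. In these comparisons, rose and fell mean higher or lower than in control cells of the same day. Where a probe was undetected on all 3 arrays of 1 group, the fold is given as "at least": the dim group was set to the detection floor of each array or to its own level, whichever was higher.

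The gene lists, the contrasts, the rule for named genes and the alternatives, except the test of every probe on its own, were fixed before the data were examined. The 18 lists cover the naive pluripotency network, general pluripotency, the LIF and STAT3 pathway, primed epiblast, trophectoderm, primitive and extraembryonic endoderm, primitive streak and mesoderm, neural and ectoderm, fibroblast and mesenchymal markers, oxidative phosphorylation and TCA cycle, glycolysis, cell cycle and proliferation, p53 targets and apoptosis, interferon response, heat shock and unfolded protein stress, two-cell-like genes, germline and meiosis, and ribosomal proteins. Esrrb is in none of them. Klf4 and Gbx2 stand in both the naive pluripotency list and the LIF list. T, Eomes and Foxa2 of the primed epiblast list and Gata2 of the trophectoderm list each stand in another lineage list. Lists were tested with camera at its preset correlation of 0.01, adjusted over the lists of a contrast. The alternatives were an estimated correlation and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes.

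The rule for named genes took Esrrb, Pou5f1, Sox2 and Nanog, the 10 largest rises and 10 largest falls per day among called genes whose 3 arrays per group do not overlap, and up to 4 members of each list with the lowest adjusted p. For differences between days and for the control time course it took the 5 largest in each direction. Names of clones, accessions and predicted loci were left out. Fbxw5, which the rule takes at day 6, is not discussed because its standard error was 1.02. Some other genes that the rule takes are not reported here.

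Pairing of arrays was checked on the residuals of the fit. On each day every GFP array correlated more closely with the Esrrb array of its own BeadChip (r across genes from 0.08 to 0.26) than with those of the other BeadChips. The ranges overlap, since at day 2 a pair from different BeadChips reached 0.09 and 1 pair of the same BeadChip lay at 0.08. Because each BeadChip held all 6 groups, a fit with the replicate number as a block, which is also the BeadChip as a block, is reported beside the counts. Other alternatives were no background correction, median centring in place of quantile normalization, no filter, detection p under 0.01 on all 18 arrays, the mean of all probes of a gene, array weights, only the arrays of the days compared, the authors' values, and each array left out in turn.

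The procedure was tested on simulated data for the day 2 comparison with 14531 genes. It recovered 3 of 50 genes changed 1.2-fold, 32 of 50 changed 1.5-fold, 48 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 3 false calls. A naive pluripotency list shifted by -0.5 was called by camera, and 0 of 17 other lists were. The simulated noise was independent between genes and arrays, with 1 SD per gene for all days and no BeadChip effect. It therefore does not show how many false calls arise with correlated genes, BeadChip effects or a larger spread at day 2.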

Results

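Gene expression was measured in E14 mouse embryonic stem cells, an established line, after transfection of a plasmid that expresses an shRNA against Esrrb, an orphan nuclear receptor of the pluripotency network. Control cells received a plasmid with an shRNA against GFP. The cells grew on gelatin in medium with serum and LIF, the cytokine that keeps mouse embryonic stem cells undifferentiated. RNA was taken at days 2, 4 and 6, with 3 replicates per shRNA and day, which gave 18 arrays. Each array measured 46643 probes at a median of 37 beads per probe, and 14531 genes were tested.

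The first principal component of the tested genes held 35.8% of the variance and followed the day. The second held 31.0% and parted Esrrb shRNA from GFP shRNA on all 3 days.

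**Figure D1:**
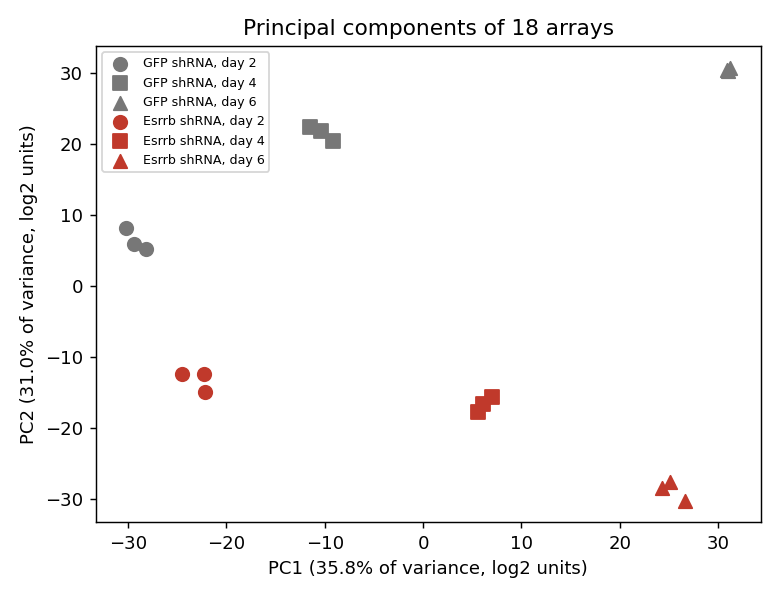
First 2 principal components (log2 units) of the 14531 tested genes, 1 point per array, coloured by shRNA and marked by day. The 6 groups of 3 arrays lie apart, with PC1 (35.8% of the variance) ordered by day and PC2 (31.0%) by shRNA.

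The first question was how the transcripts of knockdown cells differed from those of control knockdown cells at day 2. Esrrb itself fell to 21.3% of its level in GFP shRNA cells (log2 fold change -2.23, SE 0.11, n = 3 per group, limma adjusted p = 4.36e-11). Its second, dim probe did not change (-0.14, SE 0.12), and the mean of both probes gave -1.18. Klf4, a Krüppel-like factor of the naive pluripotent state, fell 3.16-fold (SE 0.11 in log2), and Bmp4, a ligand that acts with LIF in self-renewal, fell 3.45-fold (SE 0.09). Inhbb, a subunit of activin and inhibin, fell 4.04-fold and Cobl, an actin nucleator, fell 4.95-fold. The homeobox gene Msx1 rose 3.83-fold (SE 0.13), the interferon-inducible GTPase gene Irgm1 2.91-fold (SE 0.14) and the imprinted noncoding RNA H19 2.89-fold (SE 0.13).

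Of 19 measured members of the naive pluripotency network, 12 fell, 0 rose and 7 did not pass at day 2 (15 fell and 1 rose when adjusted over the list alone). Their median change was -0.55, and camera called the list (adjusted p = 7.72e-14). Jam2, an adhesion molecule of naive cells, changed by -1.63 (SE 0.10), and the transcription factor genes Tbx3 and Tfcp2l1 by -1.44 (SE 0.11) and -1.16 (SE 0.09). Sox2, a core pluripotency factor gene, changed by -0.55 (SE 0.09, adjusted p = 3.67e-04). Nanog was at -0.29 (SE 0.10, adjusted p = 0.0619), which did not pass. It passed with the replicate block (adjusted p = 0.0233), with the mean of its probes (0.0027) and without replicate 1 of the control (0.0494). It also passed without background correction (0.0261) and with the stricter filter (0.0448). Among the settings where it did not pass were median centring (0.490) and the day 2 arrays alone (0.209). Pou5f1 was at -0.02 (SE 0.09, adjusted p = 0.941).

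Trophectoderm and primed epiblast genes rose at day 2. In the trophectoderm list, 12 of 21 members rose, 2 fell and 7 did not pass (14 rose and 2 fell when adjusted over the list alone; median 0.64, camera adjusted p = 9.07e-09). The cytokeratin genes Krt7, Krt8 and Krt18 rose by 1.45, 1.15 and 0.79 in log2 (SE 0.10 each). Of 12 primed epiblast genes, 7 rose and 5 did not pass (9 rose when adjusted over the list alone; median 0.48, camera adjusted p = 3.13e-07). Among them was Pou3f1, a POU factor gene of the primed epiblast (1.11, SE 0.10).

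Glycolysis genes fell in 6 of 17 members, with 0 rises, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.0033). Examples were Ldhb, a lactate dehydrogenase subunit (-0.93, SE 0.11), and Pfkp, a phosphofructokinase (-1.05, SE 0.14). The list median was smaller with median centring (-0.01) and lay at -0.21 without replicate 1 and at -0.18 without replicate 3 of the control, at -0.15 without replicate 1 and at -0.15 without replicate 3 of the Esrrb arrays. Of 14 interferon response genes, 4 rose and 10 did not pass, also over the list alone (median 0.23, camera adjusted p = 0.0032), among them Irf1 (1.13, SE 0.10) and Ifitm3 (0.77, SE 0.09). Without the filter on dim probes the interferon median was 0.02. Of 21 p53 targets, 6 rose and 15 did not pass, also over the list alone (median 0.13, camera adjusted p = 0.0177). Eda2r (0.70, SE 0.10) and Trp53inp1 (0.64, SE 0.10) were among them. The p53 call was lost without replicate 3 of the control (median 0.05, camera adjusted p = 0.0659). It was also lost without replicate 2 of the Esrrb arrays (adjusted p = 0.0624) and with the stricter filter (adjusted p = 0.0736).

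In all, limma called 1765 genes at day 2, 959 higher and 806 lower, of which 64 and 81 changed at least 2-fold. Within the BeadChips, the direction was the same on all 3 for 99.2% of them, which is no independent support, since the calls come from the same arrays. The count was 2194 with the replicate block and 862 when only the arrays of day 2 were fitted. Replicates spread more at day 2 (median SD 0.16) than at days 4 and 6 (0.13 each). The spread shared by all days therefore favours calls at day 2. Without background correction, fold changes of dim genes shrank: Msx1 (1.23), Fgf5 and Cxcl12 still passed, while the germline gene Dazl (-0.28, adjusted p = 0.0582) and the fibroblast gene Dcn (adjusted p = 0.108) no longer did. The trophectoderm median was 0.40 in that setting and 0.41 without the filter.

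At day 4 the same comparison asked what had changed after 2 further days. Esrrb was at 15.2% of its control level (-2.72, SE 0.11, n = 3 per group, limma adjusted p = 3.92e-13; -1.34 with the mean of both probes). Acta2, smooth muscle actin, rose by 3.80 in log2 (SE 0.15, detected on 2 of 3 control arrays) and Acta1, skeletal muscle actin, rose at least 8.28-fold. Krt8 rose 6.96-fold (SE 0.10), the imprinted growth factor gene Igf2 6.67-fold (SE 0.12), H19 6.61-fold (SE 0.13) and the chemokine gene Cxcl12 6.59-fold (SE 0.17). Psmb8, an immunoproteasome subunit, rose at least 7.53-fold, but by 2.01 in log2 with the mean of its probes and by 2.00 without background correction, a setting that put Acta1 at 2.24. The largest falls included Cobl (8.19-fold, SE 0.11) and Esrrb itself, and Bmp4 fell 5.66-fold (SE 0.09). Inhbb fell too, but was detected on only 1 of 3 Esrrb arrays, so its fitted 9.27-fold change rests partly on values at background.

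In the naive pluripotency network 13 of 19 members fell at day 4, 1 rose and 5 did not pass (15 fell and 2 rose when adjusted over the list alone; median -0.85, camera adjusted p = 6.89e-11). Manba, a lysosomal mannosidase, changed by -2.43, Jam2 by -2.18, Klf4 by -2.05 and Tfcp2l1 by -1.88 (SE 0.09 to 0.11). Of 15 LIF and STAT3 pathway genes, 6 fell, 1 rose and 8 did not pass (8 fell and 1 rose when adjusted over the list alone; median -0.28, camera adjusted p = 0.0015). Spry4, an inhibitor of growth factor signalling, changed by -1.06 (SE 0.09). Sox2 (-0.37, SE 0.09, adjusted p = 0.0055) and Nanog (-0.47, SE 0.10, adjusted p = 0.0014) fell, while Pou5f1 did not pass (-0.19, SE 0.09, adjusted p = 0.131). With the mean of all probes Pou5f1 passed (adjusted p = 0.0233) and Sox2 did not (0.163), nor did Sox2 with median centring (0.169).

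The trophectoderm list rose in 13 of 21 members at day 4, with 0 falls and 8 that did not pass (14 rose and 1 fell when adjusted over the list alone; median 0.58, camera adjusted p = 9.24e-11). Besides Krt8, it held Krt7 (2.26, SE 0.10), Krt18 (2.07, SE 0.10) and the homeobox gene Rhox9 (1.92, SE 0.10). Of 12 primed epiblast genes, 6 rose and 6 did not pass, also over the list alone (median 0.41, camera adjusted p = 4.36e-05). With the stricter filter the trophectoderm and primed epiblast medians were 0.95 and 0.64. Pou3f1 rose by 1.51 (SE 0.10) and Dnmt3b, a de novo DNA methyltransferase, by 0.75 (SE 0.10). Of 6 two-cell-like genes, 4 rose and 2 did not pass (5 rose when adjusted over the list alone; median 0.66, camera adjusted p = 0.0013), with Tcstv3 at 0.98 (SE 0.10) and Tmem92 at 0.85 (SE 0.11). Of 21 p53 targets, 8 rose, 2 fell and 11 did not pass (9 rose and 2 fell when adjusted over the list alone; median 0.23, camera adjusted p = 0.0029). The p53 median was 0.15 without background correction and 0.36 with median centring. Eda2r rose by 0.96 and Gadd45a changed by -0.84.

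Metabolic lists fell at day 4. Glycolysis genes fell in 6 of 17 members with 0 rises, also over the list alone (median -0.17, camera adjusted p = 0.0020), led by Ldhb (-1.92, SE 0.11) and Pfkp (-1.40, SE 0.14). Oxidative phosphorylation and TCA cycle genes fell in 6 of 34 members with 0 rises, also over the list alone (median -0.20, camera adjusted p = 3.48e-04, adjusted p = 0.0195 with an estimated correlation). Idh3a, a subunit of isocitrate dehydrogenase, changed by -0.61 (SE 0.09) and Uqcrc1, a subunit of respiratory complex III, by -0.43 (SE 0.09). Of 14 heat shock and unfolded protein stress genes, 5 fell, 1 rose and 8 did not pass, also over the list alone (median -0.25, camera adjusted p = 0.0104). That call was lost with adjusted p = 0.0713 with an estimated correlation, and the median was -0.11 without replicate 2 of the control and -0.14 without the filter. Ddit3, a stress-induced transcription factor gene, changed by -1.45 (SE 0.11), and Trib3 by -0.67 (SE 0.09). The cell cycle list was not called (camera adjusted p = 0.0592), but it was called without background correction (0.0391), without the filter (0.0073) and without replicate 3 of the control (0.0396).

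In all, limma called 3399 genes at day 4, 1791 higher and 1608 lower, with 180 and 224 changed at least 2-fold, and 3833 genes with the replicate block. The direction was the same on all 3 BeadChips for 99.5% of them. Median centring moved the median of all genes by 0.10 and gave 2430 higher and 789 lower genes, so the split by direction depends on the scaling, and under it the medians of the LIF, oxidative phosphorylation, glycolysis and heat shock lists were -0.15, -0.09, -0.10 and -0.13. Acta2 rose by 1.52 in log2 with the mean of its probes, and without background correction the two-cell-like median was 0.36.

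At day 6 the comparison covered the last time point. Esrrb was at 27.4% of its control level (-1.87, SE 0.11, n = 3 per group, limma adjusted p = 3.56e-11; -0.94 with the mean of both probes). Sp5, a transcription factor gene downstream of Wnt signals, rose by 4.39 in log2 (SE 0.14), and T, the brachyury gene of the primitive streak, by 3.59 (SE 0.12). Acta2 rose 20.4-fold (SE 0.15 in log2), Acta1 18.4-fold (SE 0.14) and Igf2 14.9-fold (SE 0.12). Cxcl12 rose at least 9.34-fold and the Wnt ligand gene Wnt8a at least 6.30-fold. The largest falls included Ldhb (6.95-fold, SE 0.11), the lipid droplet gene Cidea (6.90-fold, SE 0.15), Jam2 (5.12-fold, SE 0.10) and Cox6a2, a cytochrome oxidase subunit, which was at least 4.73-fold lower. From day 2 to day 6 Ldhb rose by 2.29 in log2 in control cells and by 0.42 in knockdown cells. Cox6a2, undetected in both arms at day 2, was detected at day 6 in control cells only. Without background correction Wnt8a was at 2.14 and Cox6a2 at -1.73 in log2.

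**Figure D2:**
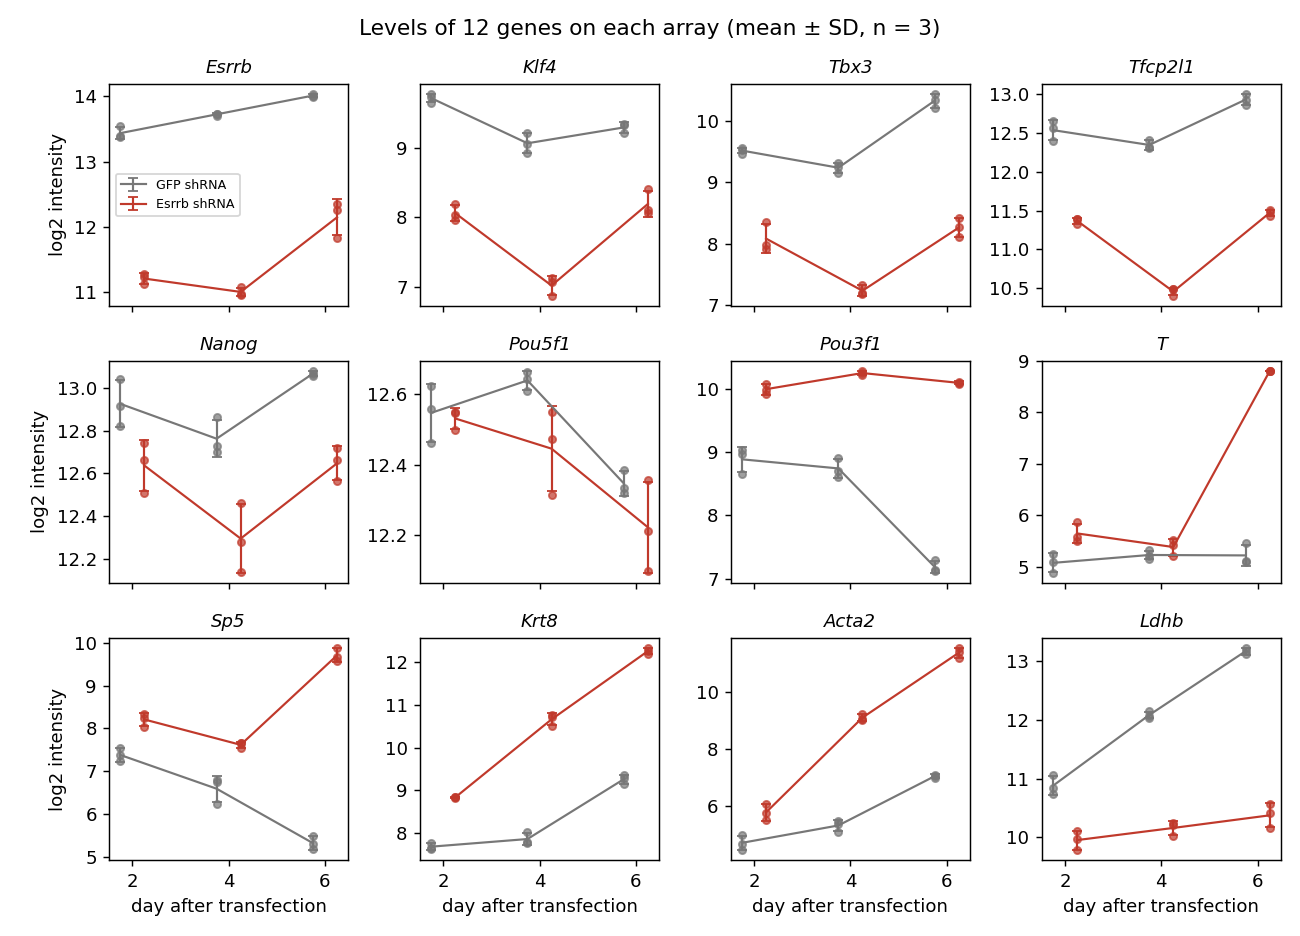
Log2 intensity of 12 genes by day in GFP shRNA (grey) and Esrrb shRNA (red) cells, with points for arrays and lines for the mean ± SD (n = 3). Esrrb lay at 21.3%, 15.2% and 27.4% of its control level at days 2, 4 and 6.

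Naive pluripotency genes fell in 12 of 19 members at day 6, 3 rose and 4 did not pass, also over the list alone (median -0.69, camera adjusted p = 5.75e-04). Tcl1, a co-activator of the kinase Akt, changed by -2.11 (SE 0.10), Tbx3 by -2.07 (SE 0.11) and Tfcp2l1 by -1.46 (SE 0.09). The general pluripotency list moved the other way: 10 of 20 members rose, 2 fell and 8 did not pass (11 rose and 4 fell when adjusted over the list alone; median 0.32, camera adjusted p = 0.0193). In control cells this list fell from day 2 to day 6 (median -0.79). Higher levels than in control cells at day 6 therefore do not show a rise over time. Lefty1, a Nodal antagonist, rose by 1.82 (SE 0.10) and the RNA-binding protein gene Lin28a by 1.47 (SE 0.12). Mybl2 changed by -1.21 (SE 0.09) and Sox2 by -0.68 (SE 0.09, adjusted p = 6.67e-06). Nanog changed by -0.42 (SE 0.10, adjusted p = 0.0018), and Pou5f1 did not pass (-0.12, SE 0.09, adjusted p = 0.292). With the mean of all probes the Sox2 call was lost (-0.24, adjusted p = 0.141) and Nanog was at -0.89, while with median centring the Nanog call was lost (adjusted p = 0.0647).

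Of 12 primed epiblast genes, 11 rose and 1 did not pass at day 6, also over the list alone (median 0.98, camera adjusted p = 4.86e-08). Besides T they included Pou3f1 (2.91, SE 0.10), Fgf5 (at least 3.78-fold, and 1.47 in log2 without background correction) and Dnmt3b (1.34, SE 0.10). The trophectoderm list rose in 13 of 21 members, with 1 fall and 7 that did not pass, also over the list alone (median 1.204, camera adjusted p = 1.76e-08). Krt8 rose by 3.00, Krt18 by 2.67 and Cdx2, the caudal homeobox gene of the trophectoderm, by 2.41 (SE 0.10 each). Of 10 neural and ectoderm genes, 6 rose, 1 fell and 3 did not pass, also over the list alone (median 0.45, camera adjusted p = 0.0069). Gap43, a growth cone protein gene, rose by 2.71 (SE 0.10) and Sox11 by 2.17 (SE 0.11). The neural call was lost with the stricter filter (adjusted p = 0.0984), and its median was -0.01 without a filter. In control cells the medians of the primed epiblast and neural lists changed by -0.22 and -0.41 from day 2 to day 6. Higher levels than in control cells at day 6 therefore need not be gains over time. From day 2 to day 6, T rose by 3.16 in log2 in knockdown cells. Pou3f1 instead lay at 9.91 to 10.08 and then 10.07 to 10.12 there, and at 8.66 to 9.03 and then 7.13 to 7.30 in control cells.

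Glycolysis genes fell in 10 of 17 members at day 6 with 0 rises, also over the list alone (median -0.61, camera adjusted p = 2.82e-05), among them Pfkp (-2.17, SE 0.14), Hk1 (-1.41, SE 0.13) and Aldoc (-1.12, SE 0.09). All 10 germline and meiosis genes fell, also over the list alone (median -0.51, camera adjusted p = 6.73e-05), with Taf7l at -1.38 (SE 0.11) and Tex11 at -1.35 (SE 0.12). In control cells the medians of the glycolysis and germline lists rose by 0.29 and 0.72 from day 2 to day 6. Lower levels than in control cells at day 6 therefore need not be losses over time. Oxidative phosphorylation and TCA cycle genes fell in 11 of 34 members, and 1 rose (10 and 1 when adjusted over the list alone; median -0.18, camera adjusted p = 0.0193). That call was lost with adjusted p = 0.119 with an estimated correlation, with median centring (0.127) and with only the day 6 arrays (0.051). Cyc1 (-0.70, SE 0.11) and Uqcrc2 (-0.57, SE 0.09), both of respiratory complex III, were among those that fell.

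**Figure D3:**
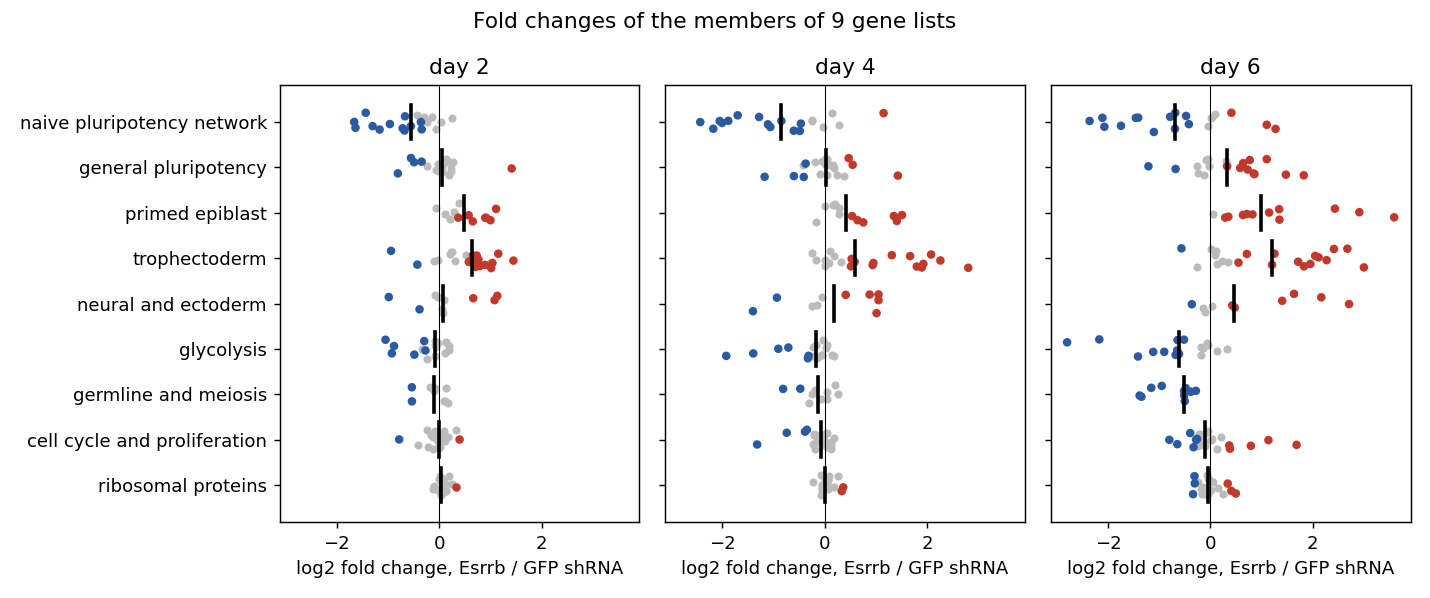
Log2 fold changes (Esrrb over GFP shRNA) of the measured members of 9 gene lists at days 2, 4 and 6, with called rises in red, called falls in blue, other members in grey and the list median as a black bar. The naive pluripotency medians lay at -0.55, -0.85 and -0.69 and the trophectoderm medians at 0.64, 0.58 and 1.204.

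In all, limma called 5952 genes at day 6, 2876 higher and 3076 lower, with 391 and 459 changed at least 2-fold, and 6382 genes with the replicate block. The direction was the same on all 3 BeadChips for 99.2% of them. With median centring 2798 genes were higher and 2351 lower, so here too the split by direction depends on the scaling. Acta2 rose by 2.69 in log2 with the mean of its probes. Without background correction the medians of the primed epiblast, trophectoderm and neural lists were 0.61, 0.73 and 0.25, and without a filter the trophectoderm median was 0.59. With the stricter filter the primed epiblast median was 0.64.

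Some lists were called on no day with the reported settings. Among 20 primitive and extraembryonic endoderm genes, 3 rose and 2 fell at day 2, 7 and 3 at day 4 and 7 and 6 at day 6 (camera adjusted p = 0.793, 0.239 and 0.961). Gata6, an endoderm factor gene, fell on all 3 days (-0.67, -0.79 and -1.12, SE 0.12), while Dab2 rose at days 2 and 4 (0.83 and 0.82, SE 0.09; 0.52 at day 2 with the mean of its probes). Among 14 primitive streak and mesoderm genes, 4 rose and 2 fell at day 2, 2 and 2 at day 4 and 5 and 4 at day 6 (0.798, 0.450 and 0.212), with T and Bmp4 moving in opposite directions at day 6. Among 12 fibroblast and mesenchymal markers, 3 rose and 0 fell at day 2, 1 and 3 at day 4 and 4 and 4 at day 6 (0.649, 0.450 and 0.320), though with the stricter filter the list was called at day 4 (median -0.38, adjusted p = 0.0142). In that list Acta2 rose, and at day 6 so did the actin-binding protein gene Tagln (at least 2.20-fold) and the lysyl oxidase gene Lox (at least 1.40-fold), while Thy1, a fibroblast surface antigen, fell at days 4 and 6 (-0.80 and -1.46, SE 0.10). Among 26 cell cycle genes, 1 rose and 1 fell at day 2, 0 and 4 at day 4 and 5 and 6 at day 6. Ccnd3, a D-type cyclin gene, fell at days 2 and 4 (-0.78 and -1.32, SE 0.10), and Ccnd2 rose at day 6 (1.68, SE 0.11). Among 22 ribosomal protein genes, 1 rose at day 2, 2 rose at day 4, and 3 rose and 3 fell at day 6.

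The remaining lists not called on a given day had these counts. General pluripotency genes rose in 1 and fell in 4 of 20 members at day 2 and rose in 3 and fell in 4 at day 4. LIF and STAT3 genes rose in 1 and fell in 4 of 15 members at day 2 and rose in 3 and fell in 6 at day 6, with Socs3, a direct feedback inhibitor of STAT3, at -1.05 (SE 0.09) at day 6. Neural genes rose in 3 and fell in 2 of 10 at day 2 and rose in 5 and fell in 2 at day 4. Of 34 oxidative phosphorylation genes, 0 passed at day 2, but with the replicate block Sdhb (0.32, adjusted p = 0.0489), Uqcrc1 (-0.28, 0.0440) and Ndufb5 (-0.40, 0.0215) did. Of 21 p53 targets, 7 rose and 3 fell at day 6. Of 14 interferon response genes, 4 rose and 1 fell at day 4, and 4 rose and 3 fell at day 6. Of 14 heat shock genes, 2 rose and 1 fell at day 2, and 2 rose and 5 fell at day 6. Of 6 two-cell-like genes, 1 rose at day 2 and 3 rose at day 6 (camera adjusted p = 0.0623 at day 6, and 0.0077 without the filter). Of 10 germline genes, 2 fell at day 2 and 2 at day 4. The median, mean and test of a list differed in sign for general pluripotency, LIF, endoderm, streak, fibroblast and cell cycle genes at day 2, for fibroblast and ribosomal genes at day 4 and for endoderm, cell cycle and heat shock genes at day 6, and none of these was called. With an estimated correlation, all called lists held except heat shock at day 4 and oxidative phosphorylation at day 6.

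The overlap between days asked whether the genes changed on different days were shared. Days 2 and 4 shared 1096 genes called in one direction, where chance gives 118.2 higher and 89.2 lower, and 32 were called in opposite directions, where it gives 205.5 (r = 0.62 across genes, which are not independent replicates). Days 4 and 6 shared 2279 in one direction and 123 in opposite directions (r = 0.69), where chance gives 354.5 higher, 340.4 lower and 697.4 opposite. Days 2 and 6 shared 1013 and 180 (r = 0.42), where chance gives 189.8, 170.6 and 362.5. With the replicate block the counts in one direction were 1287, 2543 and 1200. On all 3 days 409 genes were higher and 426 lower, among them Krt8 and H19 higher and Jam2, Cobl and Kdelr3 lower.

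A further question was which effects differed between days, tested as the difference itself. From day 2 to day 6 the effect of the knockdown rose for Sp5 (log2 difference 3.56, SE 0.19) and T (3.01, SE 0.18, detected on 2 of 3 control arrays at day 2), and dropped for the prolyl hydroxylase gene Egln3 (-2.40, SE 0.13) and Ddit3 (-2.37, SE 0.15). Acta1, Acta2 and Cox6a2 were called as well but were undetected in control cells at day 2, so no size is given, and Egln3 was at -1.09 with the mean of its probes. From day 4 to day 6 the effect rose for T (3.43, SE 0.18, limma adjusted p = 3.79e-10) and Sp5 (3.37, SE 0.19, adjusted p = 1.73e-09). From day 2 to day 4 the effect rose for Krt8 (1.65, SE 0.14) and, again without a size, for Acta1 and Acta2. It dropped for Ddit3 (-1.96, SE 0.15) and Nupr1, a stress-induced chromatin protein gene (-1.64, SE 0.14). Between days 2 and 6 the effect rose for the primed epiblast (median 0.60), trophectoderm (0.56), neural (0.46), general pluripotency (0.34) and streak (0.15) lists. It dropped for the germline (-0.61) and glycolysis (-0.42) lists, and camera called these 7 lists with an estimated correlation too.

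In all, limma called 3664 genes for the difference between days 2 and 6 (1643 up, 2021 down), 700 between days 2 and 4 (337 up, 363 down) and 2081 between days 4 and 6 (898 up, 1183 down). With the replicate block they were 4169, 1034 and 2520, and with median centring the splits became 346 up and 135 down between days 2 and 4 and 416 up and 1086 down between days 4 and 6.

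Control cells gave the background of change over time. Between days 2 and 6 in GFP shRNA cells, the stress-induced genes Nupr1 and Ddit3 rose 12.9-fold (SE 0.10 in log2) and 12.4-fold (SE 0.11), and Got1l1 rose 6.99-fold (SE 0.11). Soga3 fell 7.57-fold (SE 0.11) and Grhl2, a grainyhead-like factor gene of epithelia, fell 6.38-fold (SE 0.11). In the general pluripotency list 13 of 20 members fell and 1 rose (15 and 2 when adjusted over the list alone; median -0.79, camera adjusted p = 1.80e-05). Of 21 p53 targets, 13 rose and 1 fell (14 and 1 when adjusted over the list alone; median 0.50, camera adjusted p = 0.0013). The endoderm list rose in 12 of 20 members and fell in 1, also over the list alone (median 0.58, camera adjusted p = 0.0013, adjusted p = 0.0598 with an estimated correlation). The calls of the neural (median -0.41), primed epiblast (-0.22), glycolysis (0.29) and germline (0.72) lists were likewise lost, with adjusted p = 0.0598, 0.0744, 0.0697 and 0.0697 with an estimated correlation. The primed epiblast call (adjusted p = 0.0477) was lost with the replicate block too (0.0648). The limma count was 7125 genes, 3765 higher and 3360 lower (7628 with the replicate block), and 4181 higher and 2246 lower with median centring.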

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

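The tests of array spread, scaling, the 2 time courses, plasmid uptake, plasmid dilution and fibroblasts were chosen only after the results were seen, while the regroupings of day labels were planned.

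The effect of the knockdown differed between days, by limma's test of the difference itself, for 700 genes between days 2 and 4, 3664 between days 2 and 6 and 2081 between days 4 and 6. Between days 2 and 4 the differences in log2 included Krt8 1.65, Ddit3 -1.96, Nupr1 -1.64 and Misp3 -1.51. Between days 2 and 6 they included Sp5 3.56, T 3.01, Egln3 -2.40, Ddit3 -2.37, Fcgrt -2.26 and Aurkc -2.19. Between days 4 and 6 they included T 3.43, Sp5 3.37, Ccnd2 2.03, Pygl -1.71 and Dnaic1 -1.70. Acta1, Acta2 and Cox6a2 were called between days 2 and 6 too, and Acta1 and Acta2 were called as rises between days 2 and 4. These genes were undetected on all 3 control arrays of day 2, so no size is given. The effect on 7 gene lists differed between days 2 and 6 by camera, with a median difference of 0.34 for general pluripotency, 0.60 for primed epiblast, 0.56 for trophectoderm, 0.15 for primitive streak and mesoderm, 0.46 for neural and ectoderm, -0.42 for glycolysis and -0.61 for germline and meiosis.

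Among 100 groupings of the day labels within each shRNA, the real one included, 6 gave as many genes as the 700, 7 as many as the 3664 and 5 as many as the 2081, so chance was not excluded by this test. The highest other counts were 1310, 7852 and 2827. All of the as large regroupings (5, 6 and 4) had moved the days of the 2 shRNA arms in opposite directions, which puts the change that both arms shared over time into the difference and points to that structure of the samples. The highest counts among the other regroupings were 557, 2492 and 1488, under the real counts.

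A first pattern was that 5952 genes were called at day 6 against 1765 at day 2. A smaller spread between arrays at day 6 (median SD 0.13, against 0.16 at day 2) is argued against as the whole cause, because the SD of the fold changes of all genes was 1.83 times as large at day 6 as at day 2. The lowest ratio of the day 6 to the day 2 count over the scalings was 3.11, so scaling alone did not make the pattern. Among the 3664 genes whose effect differed, 54.3% changed between days 2 and 6 in knockdown cells and 76.2% in control cells. Neither share decides much, since 5388 of all 14531 genes changed in knockdown cells and 7125 in control cells. By calls, 1579 of the 3664 changed in control cells only, 775 in knockdown cells only and 1214 in both. A change in control cells alone is thus argued against for the 775. In the 1214 both arms changed, and for the 1579 a change in control cells alone stays open. Against control arrays of the same day, the SD of the fold changes was 0.28, 0.38 and 0.51 at days 2, 4 and 6, so the measured difference between the arms grew. Array position and other effects of the Esrrb shRNA, which cannot be told apart from the group, stay open as parts of it.

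A second pattern was a signal in data outside the tests of genes: the control probe named for ampicillin resistance, a gene such plasmids carry, was brighter in Esrrb shRNA cells at day 6. It was undetected in control cells at day 6 and detected on 3 of 3 Esrrb arrays, which makes it at least 2.56-fold higher. The probe is known here by its name alone, without its sequence. The arguments on plasmid uptake and dilution hold only if it measures the plasmid and no other signal adds to it. Scaling is argued against, because the dimmest Esrrb array was 1.62 times as bright as the brightest control array before normalization, and so is more plasmid taken up at transfection, because the difference at day 6 exceeded that at day 2 by at least 1.25 in log2. Division that slowed at a constant rate from day 2 on would have given at least 0.62 of growth from day 2 to day 4, where 0.11 (SE 0.19) was seen. Such log2 differences cannot show an added signal of fixed size under a brighter one. The mean raw intensity was 321.4 in Esrrb shRNA and 255.8 in GFP shRNA cells at day 4, and 136.0 and 67.7 at day 6. A raw gap of similar size was thus present at day 4, so the onset of the difference is not settled. A slowing after day 4 and array position may each account for it and were not tested.

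The last pattern was the rise of Acta1, Acta2, Krt7, Krt8 and Krt18 at days 4 and 6. Fibroblasts in the knockdown cultures are argued against as its cause only if the collagen probes work. The 5 probes for Col1a1, Col1a2 and Col3a1, genes that fibroblasts express abundantly, were detected on 0 of 18 arrays. No array here shows these probes detecting their transcripts, so how few fibroblasts they would reveal is not known. Tagln and Lox of the fibroblast list did rise at day 6, but like Acta2 they are not expressed by fibroblasts alone. Scaling is argued against by the lowest median change of the 5 genes at day 6 over the scalings, 2.91 in log2. The knockdown itself, other effects of the Esrrb shRNA and array position stay open, as these cannot be told apart here. No biological explanation was tested.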

How the results depend on the processing

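The alternative in which every probe was tested on its own was chosen after seeing the data, to compare with the authors' values, whose unnamed probes could not give Esrrb, list or named-gene values. Of 244 alternative counts, 241 stayed within 1.5 times the reported count and 3 moved: fry called 15 lists at day 4 (9 reported) and 15 at day 6 (8 reported), since it asks only whether a list moves on balance, and fitting only the arrays of day 2 gave 862 genes in place of 1765, where the cause was not tested. That setting gave more genes at day 4 (3553) and day 6 (6396), and the median SD between replicates was higher at day 2 (0.16) than at days 4 and 6 (0.13 each). A spread shared by all days thus tends to understate that of day 2, so the 1765 genes may be too many. Esrrb kept its direction and call in all 42 alternatives. The replicate block, which is also the BeadChip block, kept every count within 1.5 times (2194, 3833 and 6382 genes at days 2, 4 and 6) and ended no call of a named gene or of a list on a day; it made 7 named genes pass (Nanog, Sdhb, Uqcrc1, Ndufb5, Ccnd2 and Hspb1 at day 2 and Tmem92 at day 6), and in the control time course it ended the primed epiblast call (adjusted p = 0.0648). Leaving out each array gave 1355 to 1791, 2610 to 3154 and 5120 to 5383 genes at days 2, 4 and 6, 476 to 822, 3003 to 3596 and 1619 to 1956 for the differences of days 2 and 4, 2 and 6 and 4 and 6, and 6284 to 6787 in the control. The authors' values gave 1865, 3764 and 7897 probes at days 2, 4 and 6, against 1856, 3705 and 7213 when every probe was tested on its own. Of the list results, 835 kept their direction and their side of the threshold, though their values could move, 21 passed and 8 no longer passed, and of the named-gene results 4235, 40 and 107. Reversed were Dcn at day 2 without a filter (-0.11 in log2, adjusted p = 0.755), Rps19 at day 4 (0.25) and Rps24 at day 6 (-0.084), both with the mean of all probes. For a fold change these settings alter only which probes stand for a gene. The reversals thus come from probes of the same gene that differ, and why they differ was not tested. Signal over background limits dim genes: without background correction 50 named-gene results moved by over 1.5 times, and 3 of these no longer passed.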

Other observations

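The comparison of the 2 time courses was chosen only after the results were seen, and the other splits of the arrays were planned.

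Some named genes changed over time to different degrees in the 2 arms. From day 2 to day 6, Ddit3 rose by 3.63 in log2 (SE 0.11) in control cells and by 1.26 (SE 0.11) in knockdown cells, and Nupr1 by 3.69 and 1.53 (SE 0.10). Krt8 rose by 1.58 and 3.42 (SE 0.10). Acta2, undetected in control cells at day 2, rose at least 4.00-fold in control cells and by 5.63 in log2 (SE 0.15) in knockdown cells. Igf2 rose by 2.49 (SE 0.12) in knockdown cells and was at -0.17 in control cells, where it did not pass (limma adjusted p = 0.238). Sp5 went in opposite directions, at -2.06 in control cells and 1.50 in knockdown cells (SE 0.14).

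One hypothesis was that both arms followed the same time course. Across genes, which are not independent replicates, the change from day 2 to day 6 in knockdown cells rose with that in control cells with a slope of 0.49 (r = 0.59, rho = 0.56), which argues against equal change. Between these days 5388 genes changed in knockdown cells and 7125 in control cells, with 3287 changed in one direction in both and 353 in opposite directions. Noise in the control changes lowers such a slope too, but the 3664 genes whose effect differed between these days also argue against equal change.

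Other control probes, named for alkaline phosphatase, a T7 primer antisense and beta-galactosidase, were detected at day 2 and on 0 arrays of either arm at day 6. The ampicillin resistance probe was at 11.8, 7.86 and 4.62 in log2 in control cells and at 11.9, 8.08 and 6.36 in knockdown cells at days 2, 4 and 6.

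For each day and for the control time course, 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05. The real split was the 1 of 10 with as many genes: 1765 at day 2 (highest other 7), 3399 at day 4 (highest other 0), 5952 at day 6 (highest other 1) and 7125 in the control (highest other 0). For the lists, 1 of 10 splits gave as many: 6 at day 2 (highest other 4), 9 at day 4 (highest other 7) and 8 at day 6 (highest other 6). The 3 other splits that part all pairs of a BeadChip gave 0 genes on each day, but up to 4, 5 and 6 lists at days 2, 4 and 6. Every other split mixes both groups in each set of 3, so the real difference widens the spread within the sets and partly remains between them. Few called genes were therefore to be had in any case, and these splits give no rate of false calls for genes or lists. For the overlaps, 1 of 100 groupings within each day, the real one, gave as many genes as 1096, 1013 and 2279, with highest others of 0, 3 and 0. In no other grouping did both days call over 0, 7 and 0 genes, so this test could not come out otherwise and says nothing about sharing between days.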
